A study of Homo sapiens with 9 samples.

How the data were processed

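Expression was measured in SKOV3 cells in 3 groups of 3 arrays each, a vector control and 2 hairpins against EZH2, per the labels. RNA was extracted with Trizol, amplified and labelled with the dye Cy3, per the labels' protocols. Samples were grouped by the labels' genotype field and named by group and replicate number. The control arrays lay on slide 1, shEZH2.1 replicates 1 and 2 on slide 2, and shEZH2.1 replicate 3 with the 3 shEZH2.2 arrays on slide 3. Arrays were Agilent single-colour arrays with 41000 probes. Images were read with Feature Extraction 9.5.3.1, per the file headers. The processed signal used here is an intensity on a linear scale that the software had corrected for spatial trends and background and not scaled between arrays, per the file headers. The raw mean spot signal and the local background median, also deposited as intensity, were used for an alternative. The authors' series matrix holds log2 values, and each of its 9 columns had a median of 7.86. Set against each array's scanner values, its columns had rank correlations of 1 and slopes of 0.999 to 1.038 with the log2 raw mean signal, and all columns shared the same quartiles. Its scale was therefore taken as log2 and its centring as quantile normalization, and its direction is that of signal. Its background correction and its software are not given in the sources used here.

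The 75th percentile of signal lay between 1531.2 and 2070.6 on the 9 arrays, and 1 spot was saturated on each. Control spots were left out, as were the spots with outlier flags, between 52 and 202 per array (202 on shEZH2.1 replicate 3). No 2 arrays of a group held identical values, and arrays of a group differed by a median absolute log2 value of 0.078 to 0.119. The number of arrays limits the precision.

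From the files, log2 of the processed signal minus the array's 75th percentile was computed. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 32835 probes. Probes were named through their accession in a RefSeq gene table of assembly GRCh38.p14 (23434 probes), a current symbol (2317) or an older symbol (1043), and 14206 kept the name in the file. That table was used for names and for the order of neighbouring genes only. Probe coordinates are those in the file headers' annotation, on hg17, and exon annotation of that build was not used here. For each gene name the brightest passing probe was taken, which gave 24624 names, 15153 of them with a RefSeq symbol. Probes of 18 names were called in opposite directions in the mean of both hairpins.

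One linear model over all 9 arrays was fitted with limma 3.58.1 (lmFit and eBayes, 6 residual degrees of freedom) in R 4.3.3, with data.table (version 1.17.8) and statmod 1.5.0. Contrasts were each hairpin against control, the mean of both against control, and shEZH2.1 minus shEZH2.2. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold, and "rose", "fell" and "changed" are used of called genes. Errors of single genes are standard errors from this model. For 33 gene lists, called members were counted over all genes tested and adjusted over the list alone. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 33 lists within each contrast. Symbols of list members were matched through older symbols. The groups, the tests of the comparisons, the alternatives, the gene lists and the rule for named genes were set before the data were examined. Tests of explanations for single patterns were in part chosen later, as stated with them.

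Named genes were EZH2, ALDH1A1, SSTR1 and DACT3, the 12 rising and 12 falling genes with the largest smaller change of both hairpins, the 5 rising and 5 falling genes with the largest change for each hairpin, and the 8 higher and 8 lower genes with the largest difference between hairpins that were also called against control with at least 1 hairpin. Up to 4 members of each list with the largest change in the mean of both hairpins were added. Names without a gene symbol, probes not well above background on all 3 arrays of at least 1 compared group, and genes with probes called in opposite directions were passed over for the next gene, a gene in 2 parts counted under both, and Y-linked genes and XIST were left out. Not every gene this rule allows is named.

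The fit and the list tests were tested on simulated data with the 24624 genes. For shEZH2.1 against control, 92% of 100 genes changed 2-fold and 97% of 100 genes changed 4-fold were called, and 1 of 24396 unchanged genes was. For shEZH2.2 against control the shares were 91% and 97%, with 8 unchanged genes called. For the mean of both hairpins they were 92% and 98%, with 2 unchanged genes called. Of 33 lists, 1 was called, the one shifted by 0.3 on the log2 scale. Genes were simulated as independent of each other, so this does not show how the list test behaves where members vary together.

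Alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median, no scaling, the authors' matrix, no filter, a filter on all 9 arrays, other limits on adjusted p and fold, all probes singly, the mean of a gene's probes, an intensity trend in eBayes, the slide as a random or fixed block, slide 3 alone, the replicate number as a block, only the arrays of the groups compared, averaged groups, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.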

Results

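Gene expression was measured in SKOV3, an established human epithelial ovarian cancer cell line, after knockdown of EZH2 with short hairpin RNAs. Cells had received a lentivirus carrying a vector control or either of 2 hairpins against EZH2, called shEZH2.1 and shEZH2.2 here, and uninfected cells had been removed with puromycin. Each of the 3 groups held 3 single-colour arrays. The series design calls these technical replicates, so the p-values measure the technical spread between arrays and not the spread between cultures. Each array read 41000 probes, of which between 77.2% and 81.9% were well above background. Arrays of the same group correlated across probes, which are not independent replicates, at r between 0.9958 and 0.9978. The number of arrays limits the precision. In a principal component analysis the first component held 52% of the variance and set the shEZH2.2 arrays (55.1 to 59.7) apart from the other 6 arrays (-29.7 to -26.1). The second component held 30% and set the control arrays (34 to 41) apart from the shEZH2.1 arrays (-43.6 to -26.6). On the third component, with 5.4%, shEZH2.1 replicate 3 lay at -31.4 and the other shEZH2.1 arrays at 7.7 and 17.1, and 193 genes differed between that array, on slide 3, and the other 2, on slide 2, where the lone array is assumed to vary like the others.

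EZH2, the catalytic subunit of Polycomb repressive complex 2 and the target of both hairpins, fell with each of them. Its brighter probe (hg17 chromosome 7, 147942169 to 147942228) had a log2 level of 2.66 ± 0.055 (SD, n = 3, range 2.6 to 2.71) in control arrays, relative to each array's 75th percentile. The level was 1.12 ± 0.026 (SD, n = 3, range 1.09 to 1.15) with shEZH2.1 and 0.93 ± 0.045 (SD, n = 3, range 0.88 to 0.97) with shEZH2.2, which are 34.5% and 30.2% of control. The log2 fold changes were -1.54 and -1.73 (SE 0.047 for each), with limma adjusted p = 3.87e-06 and 3.45e-07. The hairpins differed in EZH2 by 0.19 on the log2 scale (adjusted p = 0.00937), which is under the 1.5-fold limit. A dimmer EZH2 probe (hg17 chromosome 7, 148008767 to 148008826) changed less, by -0.425 with shEZH2.1 (adjusted p = 0.0128, under the fold limit) and -0.87 with shEZH2.2 (adjusted p = 0.000232). With the probes averaged, the EZH2 log2 fold changes were -0.98 and -1.30. EZH2 was the only gene among the 11 tested PRC2 subunit genes to pass the test against control with either hairpin. MTF2, a PRC2 accessory subunit, was lower with shEZH2.1 than with shEZH2.2 (log2 difference -0.69, SE 0.05, adjusted p = 1.45e-05). Among 18 tested PRC1 subunit genes, RYBP fell with shEZH2.2 (-0.68, SE 0.06, adjusted p = 3.22e-05), and no member passed the test in the mean of both hairpins.

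**Figure D1:**
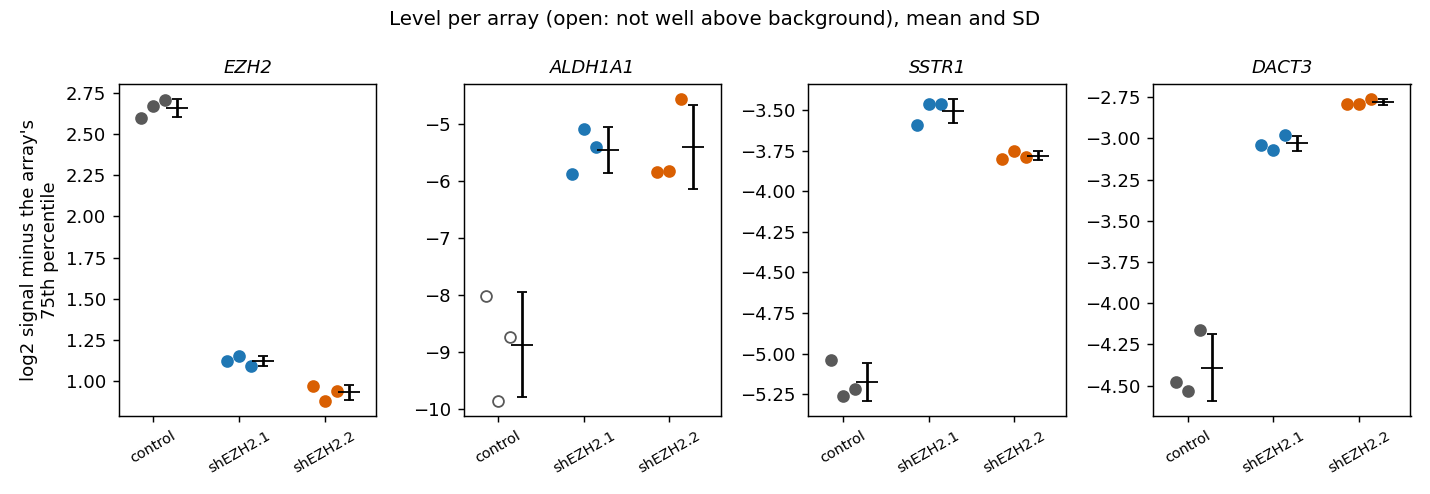
Log2 signal minus the array's 75th percentile (vertical axis) of EZH2, ALDH1A1, SSTR1 and DACT3 in the control, shEZH2.1 and shEZH2.2 groups. Each circle is 1 array, an open circle is an array on which the probe was not well above background, and the black bar is the group mean with its SD (n = 3). The EZH2 points of the hairpin arrays (0.88 to 1.15) all lie under those of the control arrays (2.6 to 2.71), and the ALDH1A1 points of the control arrays are all open.

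ALDH1A1, SSTR1 and DACT3 rose with both hairpins. These genes were remembered from a paper on this study, so their direction is not independent evidence. ALDH1A1, a retinaldehyde-oxidising enzyme used as a marker of stem-like ovarian cancer cells (hg17 chromosome 9, 72745690 to 72745749), was not well above background on any control array and was well above it on all 3 arrays of each hairpin. It was at least 4.07-fold higher with shEZH2.1 and at least 4.22-fold higher with shEZH2.2 (limma adjusted p = 0.00133 and 0.000689). Such a bound sets the bright group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal among probes well above background. That lowest signal is not a detection limit, so each fold given as "at least" holds on this signal scale only. SSTR1, a somatostatin receptor (hg17 chromosome 14, 37751725 to 37751784), rose by 1.67 and 1.39 on the log2 scale (SE 0.07 for each, adjusted p = 7.47e-06 and 2.34e-06). DACT3, an antagonist of Wnt signalling (hg17 chromosome 19, 51842746 to 51842805), rose by 1.36 and 1.61 (SE 0.09 for each, adjusted p = 4.16e-05 and 4.8e-06). Adjusted over the list alone, 3 of the 3 genes rose with each hairpin. Camera gave adjusted p = 0.00347 with shEZH2.1 and 0.0115 with shEZH2.2, and these were adjusted p = 0.264 and 0.324 with an estimated correlation. Another probe of SSTR1 was lower, with limma adjusted p = 0.0339 with shEZH2.2 and 0.213 with shEZH2.1. It was well above background on all 3 control arrays, 1 shEZH2.1 array and 0 shEZH2.2 arrays. Another probe of DACT3 went the opposite way with shEZH2.1 (-0.72, SE 0.24, adjusted p = 0.0407). With shEZH2.2 it was not called (-0.062, SE 0.243, adjusted p = 0.839). With probes averaged, the dim SSTR1 probe at its measured signal, the log2 fold change of SSTR1 was 0.55 with shEZH2.1 and 0.17 with shEZH2.2 and that of DACT3 with shEZH2.1 was 0.32, which ended those calls, and the list had adjusted p = 0.0825 with shEZH2.1 and 0.135 with shEZH2.2. After normexp background correction ALDH1A1 kept its calls with smaller log2 fold changes of 0.66 and 0.72.

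With shEZH2.1 against control, interferon-stimulated genes fell together. The lists of NRF2 antioxidant and cholesterol synthesis genes shifted upward in the camera test, with most of their members not past both limits. The comparison asks what the first hairpin changed. Of 43 interferon-stimulated genes tested, 35 fell and none rose, with a median log2 fold change of -1.70. OAS2, which senses double-stranded RNA, fell by 4.23 on the log2 scale (SE 0.35, limma adjusted p = 8.98e-05), the antiviral GTPase MX1 by 3.87 (SE 0.36, adjusted p = 0.000145) and the antiviral membrane protein IFITM1 by 4.0 (SE 0.41, adjusted p = 0.000233). Camera gave adjusted p = 1.98e-12 for this list. The members' estimated correlation was 0.836, and the list had adjusted p = 0.474 with an estimated correlation. Of 20 NRF2 target genes, 6 rose and none fell (median 0.40, camera adjusted p = 0.000197, and adjusted p = 0.121 with an estimated correlation). The aldo-keto reductase AKR1B10 rose by 3.07 (SE 0.15, adjusted p = 1.3e-05) and the heme-degrading enzyme HMOX1 by 2.63 (SE 0.15). Of 25 cholesterol synthesis genes, 7 rose and none fell (median 0.39, camera adjusted p = 2.85e-06, and adjusted p = 0.282 with an estimated correlation), among them HSD17B7 (0.88, SE 0.07). Of 50 E2F and DNA replication genes, 7 fell and none rose (median -0.32, camera adjusted p = 2.73e-09, and adjusted p = 0.264 with an estimated correlation). For all 4 of these lists the counts adjusted over the list alone were the same.

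HTRA3, a secreted serine protease, rose with shEZH2.1 by 3.89 on the log2 scale (SE 0.13, limma adjusted p = 4.25e-06). POSTN, which encodes the matrix protein periostin, was not well above background on the control arrays and was at least 3.69-fold higher (adjusted p = 1.21e-05). POSTN is also a fibroblast marker, and of 9 tested fibroblast markers, 5 rose and none fell with shEZH2.1, among them the proteoglycan genes LUM (2.31, SE 0.11) and DCN (1.60, SE 0.18). That list had a median of 0.82, or 0.72 with the members of unknown level at their bound, and camera gave adjusted p = 0.00415, which was adjusted p = 0.264 with an estimated correlation. Over genes well above background on all 9 arrays the fibroblast list had a median of 0.44 and adjusted p = 0.0852. Of 27 aldehyde dehydrogenase and retinoid genes, 8 rose and none fell (median 0.19, camera adjusted p = 0.0089, and adjusted p = 0.371 with an estimated correlation), and adjusted over the list alone 8 rose and 1 fell. ALDH2, the mitochondrial aldehyde dehydrogenase, rose by 0.71 (SE 0.06). Of 28 hypoxia and glycolysis genes, 6 fell and none rose (median -0.29, camera adjusted p = 0.00982, and adjusted p = 0.562 with an estimated correlation), with the angiogenic factor VEGFA at -0.99 (SE 0.08). Of 21 neuronal genes, 7 fell and 1 rose (median -0.58, camera adjusted p = 0.0161, and adjusted p = 0.392 with an estimated correlation). Over the settings with the same limits and 1 value per gene, between 3 and 10 members fell, 10 of them without shEZH2.1 replicate 3. MAP2, a neuronal microtubule protein, fell by 0.93 (SE 0.15).

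In all, 3514 of 24624 gene names (14.3%) passed both limits with shEZH2.1, 1338 higher (38.1%) and 2176 lower. The direction of that split depended on the processing, since 55.3% were higher after quantile normalization (1703 of 3080), 57.2% after normexp background correction (680 of 1188) and 63.8% in the authors' matrix (973 of 1525), but 35.7% with each array centred on its median and 42.7% without scaling. The control arrays lie alone on slide 1, so slide and group cannot be told apart in any comparison against control.

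With shEZH2.2 against control, genes of inflammatory signalling rose, while interferon-stimulated genes again fell. Of 30 cytokine and chemokine genes tested, 25 rose and 1 fell (median 2.13, camera adjusted p = 3.42e-11, and adjusted p = 0.181 with an estimated correlation). CSF2, the myeloid growth factor GM-CSF, rose by 6.37 on the log2 scale (SE 0.30, limma adjusted p = 2.22e-06), and the inflammatory cytokines IL1B by 5.30 (SE 0.16, adjusted p = 4.77e-07) and TNF by 3.57 (SE 0.12). SAA1, an acute-phase protein, rose by 4.57 (SE 0.17). Markers of lymphocytes and myeloid cells did not rise with it, since 0 of 10 tested rose and 2 fell (median -0.48, camera adjusted p = 0.076). Of 43 interferon-stimulated genes, 26 fell and 1 rose (median -0.92, camera adjusted p = 0.000306, and adjusted p = 0.815 with an estimated correlation). XAF1, a pro-apoptotic interferon target, fell by 3.09 (SE 0.22, adjusted p = 1.4e-05) and OAS2 by 2.48 (SE 0.35, adjusted p = 0.000552). The single member that rose was the transcription factor IRF1 (1.18, SE 0.06), which was chosen after its values were seen. For both lists the counts adjusted over the list alone were the same.

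With shEZH2.2 the lists of apoptosis and cholesterol synthesis genes shifted upward and those of replication, mitosis and NRF2 target genes downward in the camera test, with most members of each not past both limits. Of 29 apoptosis genes, 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 0.000848, and adjusted p = 0.171 with an estimated correlation). Those that rose included BMF, which promotes apoptosis (2.16, SE 0.10), and BIRC3, which inhibits it (3.19, SE 0.10). Of 25 cholesterol synthesis genes, 7 rose and 2 fell (median 0.42, camera adjusted p = 0.000252, and adjusted p = 0.438 with an estimated correlation), with HMGCS1 at 1.12 (SE 0.09). Of 50 E2F and DNA replication genes, 5 fell and 1 rose (median -0.27, camera adjusted p = 0.000495, and adjusted p = 0.47 with an estimated correlation). MCM6, a subunit of the replicative helicase, fell by 1.32 (SE 0.06). Of 48 mitosis genes, 4 fell and none rose (median -0.25, camera adjusted p = 0.000108, and adjusted p = 0.58 with an estimated correlation), among them the anaphase activator CDC20 (-0.70, SE 0.10) and the kinetochore gene SPC24 (-0.84, SE 0.07). Of 20 NRF2 target genes, 7 fell and none rose (median -0.41, camera adjusted p = 0.0333, and adjusted p = 0.305 with an estimated correlation), led by the quinone reductase NQO1 (-1.68, SE 0.05). The call of the NRF2 list ended without shEZH2.1 replicate 2 (adjusted p = 0.051), with only the arrays of the groups compared (adjusted p = 0.0679) and with probes averaged (adjusted p = 0.0662).

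The serine protease gene PRSS3 was among those that rose most with shEZH2.2 (4.84, SE 0.07, limma adjusted p = 1.31e-08). SLC6A14, an amino acid transporter, and VNN1, a pantetheinase, were not well above background on the control arrays and were at least 12.04-fold and at least 15.79-fold higher (adjusted p = 3.31e-05 and 0.000114). The basal keratin KRT5 fell by 3.61 (SE 0.19, adjusted p = 3.44e-06) and the growth factor FGF18 by 3.49 (SE 0.09, adjusted p = 2.96e-07). In all, 5256 gene names (21.3%) passed both limits, 2356 higher (44.8%) and 2900 lower. The direction of this split also depended on the processing, with 59.9% higher in the authors' matrix (1976 of 3297), 54.8% after normexp correction (1559 of 2843), 53.9% after quantile normalization (2718 of 5040) and 57.8% with a 2-fold limit, but 42.5% with arrays centred on their medians and 43.9% without scaling.

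With both hairpins, 1411 genes changed the same way, 529 higher and 882 lower. The series design states that 2 hairpins were used to limit off-target effects, so this is the comparison nearest to that purpose. The genes that rose with both hairpins included DIO2, which activates thyroid hormone (3.42 with shEZH2.1 and 3.87 with shEZH2.2, SE 0.13 for each, limma adjusted p = 6.57e-06 and 6.04e-07), and the water channel AQP3 (2.85 and 3.58, SE 0.13 for each). TLR4, the receptor for bacterial lipopolysaccharide, rose by 2.03 and 2.17 (SE 0.17 for each, adjusted p = 8.95e-05 and 2.25e-05), and its co-receptor LY96 by 1.86 and 2.41 (SE 0.20 for each, adjusted p = 0.00027 and 2.99e-05). The calcium-binding annexin ANXA10 rose by 2.36 and 2.80 (SE 0.23 for each), the membrane serine protease TMPRSS3 by 1.88 and 2.39 (SE 0.23 for each) and the matrix protease MMP3 by 1.89 and 3.23 (SE 0.18 for each). OLFM4, a secreted glycoprotein, was well above background on all 3 control arrays and on none of the hairpin arrays, and was at least 4.37-fold lower with shEZH2.1 and at least 4.36-fold lower with shEZH2.2 (adjusted p = 7.18e-06 and 1.05e-06). Most of the other named genes that fell with both are interferon-induced, among them XAF1 (-2.52 and -3.09, SE 0.22 for each), IFIT1 (-2.44 and -2.82, SE 0.30 for each), MX1 (-3.87 and -1.88, SE 0.36 for each, adjusted p = 0.000145 and 0.00268) and TRIM22 (-1.57 and -1.74, SE 0.26 for each). After normexp correction, which adds an offset of 50 and so pulls dim signals together, folds of dim genes were smaller, as for TLR4 (0.75 and 0.83) and OLFM4 (-0.94 and -0.90), and both kept their calls. CXXC4 (0.30 and 0.44), FCRL1 (-0.30 and -0.28), F13A1 (-0.34 and -0.26) and FMOD (-0.35 and -0.34), also called with both hairpins, lost both calls, and CHRNA9 (0.36) and LIPH (0.29) lost theirs with shEZH2.1.

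These 1411 genes were 40.2% of the genes changed by shEZH2.1 and 26.8% of those changed by shEZH2.2. Independent lists of these sizes would share 128 higher and 256.3 lower genes. Both comparisons use the same controls, and 100 simulations of unchanged groups against those controls gave 0 shared calls at most. The simulations held only independent technical spread. They cannot show how many calls a deviating control culture or slide would make both comparisons share. The fold changes of the hairpins correlated across genes at r = 0.399, against 0.499 in the simulations, and their covariance was 0.111 against 0.00963, a difference of 0.102. The 3 control arrays cannot be divided into parts of 2 or more, so part of the excess may come from the shared controls. With the groups kept whole and shEZH2.2 as the reference instead, control and shEZH2.1 shared 2691 calls the same way. A reference that differs from both other groups can thus give more shared calls than the 1411. Another 194 genes changed with both hairpins in opposite directions, against 365.8 for independent lists, and 107 of them were higher with shEZH2.1 and lower with shEZH2.2. The shared calls numbered 361 after normexp correction, 208 of them higher, and 478 in the authors' matrix, 320 of them higher. After quantile normalization 725 of 1224 were higher and with a 2-fold limit 165 of 284, but with arrays centred on their medians 507 of 1470 and without scaling 612 of 1549, so the direction of this split depended on the processing too.

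**Figure D2:**
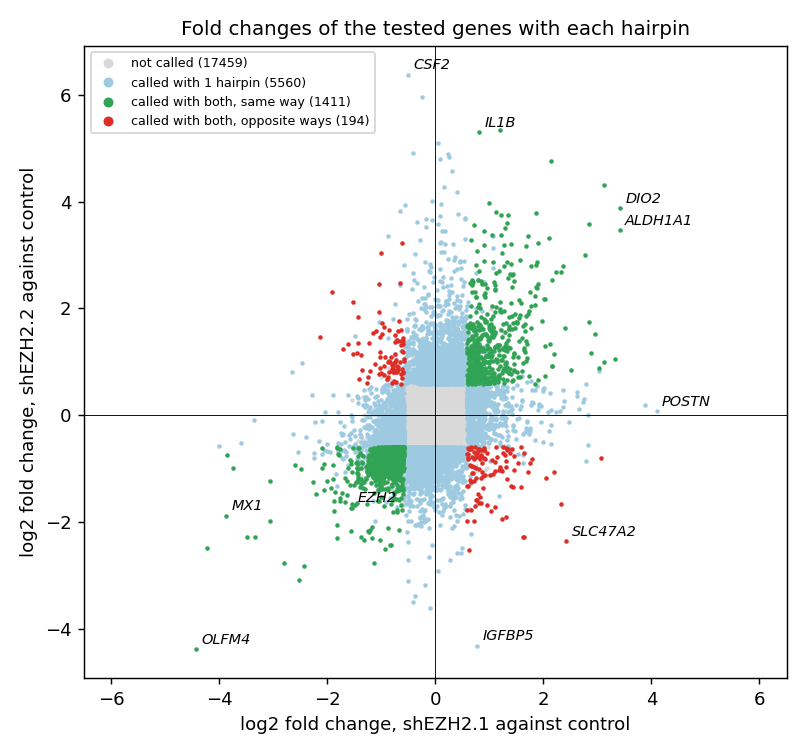
Log2 fold change of each of the 24624 tested genes with shEZH2.1 (horizontal axis) and shEZH2.2 (vertical axis) against control, 1 point per gene. Green points are the 1411 genes called the same way with both hairpins and red points the 194 called in opposite directions. OLFM4 lies far down on both axes, while CSF2 and IL1B lie high on the vertical axis alone.

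In the mean of both hairpins against control, 3373 genes (13.7%) passed both limits, 1416 higher (42.0%) and 1957 lower, and 9 of 33 gene lists shifted, the study's own list among them. With each group's arrays averaged to 1 value, which leaves 1 residual degree of freedom, limma called no gene in this comparison. The interferon-stimulated genes had 33 of 43 members lower and 1 higher (median -1.26, camera adjusted p = 9.81e-10, and adjusted p = 0.564 with an estimated correlation). MX2 fell by 2.81 (SE 0.28) and IFI44L by 2.88 (SE 0.36). The cytokine and chemokine list had 21 of 30 members higher and 1 lower (median 1.15, camera adjusted p = 9.81e-10, and adjusted p = 0.267 with an estimated correlation), although with shEZH2.1 alone it did not pass (8 higher, 3 lower, median 0.13, camera adjusted p = 0.231). The cholesterol synthesis list had 7 of 25 higher (median 0.28, camera adjusted p = 4.18e-06, and adjusted p = 0.324 with an estimated correlation) and the E2F and DNA replication list 3 of 50 lower (median -0.33, camera adjusted p = 1.36e-07, and adjusted p = 0.324 with an estimated correlation). The study's own list, which is not independent evidence (camera adjusted p = 0.00411, and adjusted p = 0.267 with an estimated correlation), had all 3 members higher. This list and the 4 remaining ones each lost their call under another setting. The study's list had adjusted p = 0.0635 with all probes tested singly and 0.0598 with probes averaged. Of 29 apoptosis genes 3 rose, or 4 adjusted over the list alone (camera adjusted p = 0.0394, and adjusted p = 0.267 with an estimated correlation), and adjusted p was 0.0561 after quantile normalization. The apoptosis list did not pass with shEZH2.1 alone (median 0.02, camera adjusted p = 0.49), and its median with shEZH2.2 was 0.28. Of 22 p53 target genes 2 rose, or 3 adjusted over the list alone (camera adjusted p = 0.0432, and adjusted p = 0.267 with an estimated correlation), and adjusted p was 0.0786 after quantile normalization and 0.0558 with the slide as a random block. The p53 list did not pass with shEZH2.1 alone (median 0.05, camera adjusted p = 0.257), and its median with shEZH2.2 was 0.38. Of 28 hypoxia and glycolysis genes 3 fell (camera adjusted p = 0.0394, and adjusted p = 0.625 with an estimated correlation). Its adjusted p was 0.052 without control replicate 1, 0.0786 without shEZH2.1 replicate 3, 0.0522 without shEZH2.2 replicate 1 and 0.0662 without scaling. Of 10 lymphocyte and myeloid markers 3 fell, among them the macrophage marker CD68 (-0.83, SE 0.06, camera adjusted p = 0.0394 for the list, and adjusted p = 0.364 with an estimated correlation), and adjusted p was 0.0572 without control replicate 1 and 0.0628 with the slide as a random block. No call of a list in any comparison held with an estimated correlation. The share of higher genes was 59.0% after quantile normalization (1805 of 3059) and with a 2-fold limit (499 of 846), 59.6% after normexp correction (722 of 1211) and 66.9% in the authors' matrix (1011 of 1512), but 39.1% with arrays centred on their medians and 43.9% without scaling.

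**Figure D3:**
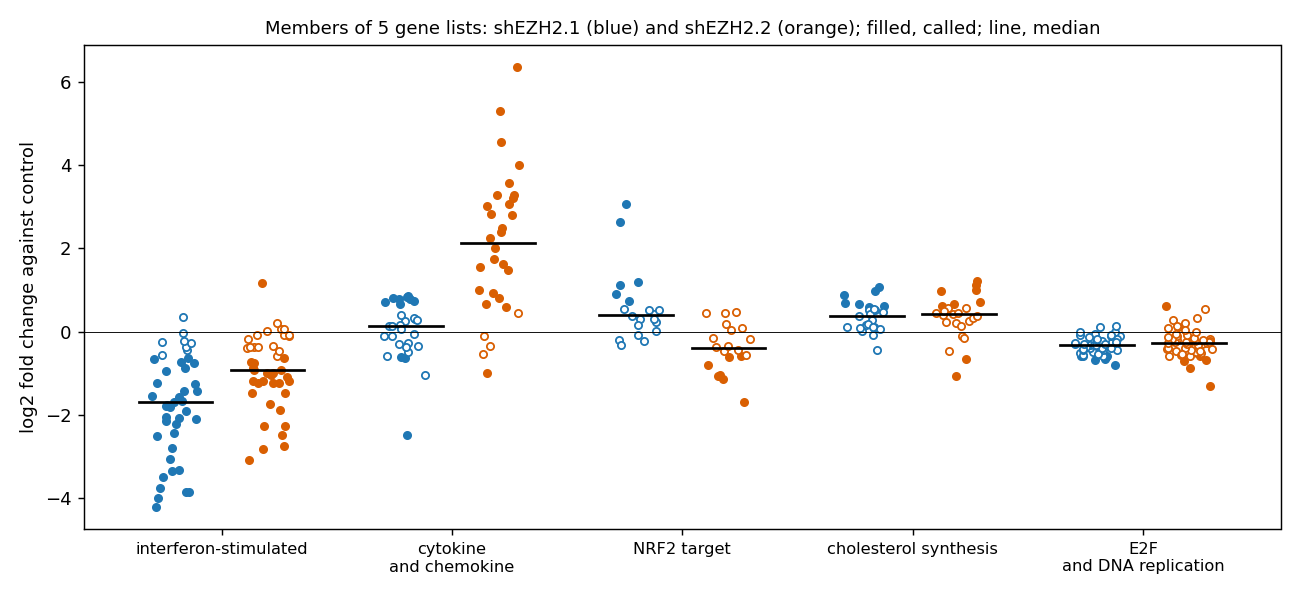
Log2 fold change against control (vertical axis) of the tested members of 5 gene lists, with shEZH2.1 in blue and shEZH2.2 in orange. Each circle is 1 gene, filled where the gene was called, and the black line is the list's median. The median of the interferon-stimulated genes is -1.70 with shEZH2.1 and -0.92 with shEZH2.2, that of the cytokine and chemokine genes 0.13 and 2.13, and that of the NRF2 target genes 0.40 and -0.41.

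Between the hairpins, cytokine and chemokine genes were higher with shEZH2.2, and the lists of NRF2 target and mitosis genes were shifted toward shEZH2.1 in the camera test. The difference asks how far the hairpins gave the same profile. Of 30 cytokine and chemokine genes, 25 were lower with shEZH2.1 than with shEZH2.2 and 1 was higher (median -2.09, camera adjusted p = 1.28e-10, and adjusted p = 0.203 with an estimated correlation). CSF2, which was well above background on 2 of the 3 shEZH2.1 arrays, differed by -6.88 with the dim array at its measured signal (SE 0.30, limma adjusted p = 1.45e-06) and IL1B by -4.49 (SE 0.16, adjusted p = 6.18e-07). Of 20 NRF2 target genes, 10 were higher with shEZH2.1 and none lower (median 0.77, camera adjusted p = 6.28e-06, and adjusted p = 0.0521 with an estimated correlation), with AKR1B10 at 3.87 (SE 0.15, adjusted p = 7.89e-07) and NQO1 at 2.23 (SE 0.05, adjusted p = 1.59e-07). The interferon-stimulated genes were lower with shEZH2.1, with 22 of 43 lower and 3 higher (median -0.74, camera adjusted p = 0.0014, and adjusted p = 0.84 with an estimated correlation). MX1 differed by -1.99 (SE 0.36). Of 48 mitosis genes, 8 were higher with shEZH2.1 and none lower (median 0.33, camera adjusted p = 6.35e-07, and adjusted p = 0.576 with an estimated correlation). Several genes moved to opposite sides of control, among them the drug transporter SLC47A2 (2.42 with shEZH2.1 and -2.36 with shEZH2.2, difference 4.78, SE 0.21, adjusted p = 1.34e-06) and ENPP2, which encodes the lysophospholipase autotaxin (1.64 and -2.28, difference 3.92, SE 0.16). The differences in these 4 lists had the same counts adjusted over the list alone.

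Differences between the hairpins also lay in apoptosis genes, where 9 of 29 were lower with shEZH2.1 and 2 higher (median -0.25, camera adjusted p = 0.0434, and adjusted p = 0.255 with an estimated correlation), and in mesenchymal genes, where 13 of 34 were higher and 2 lower (median 0.40, camera adjusted p = 0.0434, and adjusted p = 0.576 with an estimated correlation). Of 9 fibroblast markers, 5 were higher with shEZH2.1 and none lower (median 0.78, camera adjusted p = 0.103). Both calls depended on single arrays. The apoptosis list had adjusted p = 0.105 without shEZH2.1 replicate 3 and 0.0673 without shEZH2.2 replicate 3, and 0.149 with probes averaged. The mesenchymal list had adjusted p = 0.0519 without shEZH2.1 replicate 1, 0.0516 without shEZH2.2 replicate 1 and 0.0642 without shEZH2.2 replicate 3, and 0.0806 with probes averaged. Slide 3 holds 1 shEZH2.1 array, which is assumed to vary like the shEZH2.2 arrays, and the 3 shEZH2.2 arrays. Within that slide the median difference was -2.03 for the cytokine and chemokine genes, 0.75 for the NRF2 target genes and -0.83 for the interferon-stimulated genes. It was 0.38 for the mitosis genes, -0.28 for the apoptosis genes and 0.38 for the mesenchymal genes. Only the sizes of these list differences are given, since they rest on 1 shEZH2.1 array. In all, 4830 genes (19.6%) differed between the hairpins, 2403 higher with shEZH2.1 and 2427 lower. Within slide 3, 4589 genes differed, 4008 of the 4830 among them in the same direction and 0 in the opposite one, and with the slide as a fixed block 4716 genes did.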

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

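The tests of scaling, of slides and of immune-cell RNA were chosen only after the results were seen. The hairpins moved 194 genes in opposite directions against control, which by that choice differ between the hairpins by more than the fold limit. Of the 33 gene lists, 6 differed between the hairpins by the test of the difference itself. The median log2 difference, shEZH2.1 minus shEZH2.2, was -2.091 for cytokine and chemokine genes, 0.769 for NRF2 target genes, -0.742 for interferon-stimulated genes, 0.396 for mesenchymal genes, 0.33 for mitosis genes and -0.246 for apoptosis genes. None of the 6 calls held with an estimated correlation, where the adjusted p values were 0.203, 0.0521, 0.84, 0.576, 0.576 and 0.255 in the same order.

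The higher level of cytokine and chemokine genes with shEZH2.2 was weighed further. Scaling was not its whole cause, since the weakest median difference over 5 other scalings or sources of values was -1.229. The lymphocyte and myeloid markers showed no rise that RNA of immune cells would bring. Their median log2 change was -0.48 with shEZH2.2, with CD68 at -0.48 (not past the fold limit), and all 10 were in no other list. All 10 were already well above background on all control arrays, so a fall of that signal could hide a small amount of such RNA, which stays open. Within the slide that holds both hairpins the difference was -2.03, but this rests on 1 shEZH2.1 array, assumed to vary like the 3 shEZH2.2 arrays, so a difference between slides stays open. An effect of the hairpin sequence apart from EZH2, a difference between cultures and an effect of EZH2 loss that differs between them may each remain, and were not tested.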

How the results depend on the processing

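No alternative here was chosen after the results were seen. Of 213 values of the 9 main results under other settings, 190 stayed and 23 moved, by more than 1.5 times for counts and by more than the jackknife spread of 0.0301 for the correlation of fold changes. Lists and named genes were followed only in the comparisons where the main setting called them, so gained calls were not counted. Of 729 values for 33 such calls of a list in a comparison, 35 lost the call. Of 9472 values for named genes, 416 did. No direction of a called value reversed among these, while over all genes 2 called with shEZH2.2 were called the opposite way with the mean of probes. The 2-fold limit (126), normexp correction (84), the authors' matrix (60), adjusted p under 0.01 (22), leaving out control replicate 1 (20) and the mean of probes (18) ended most of these calls of lists and named genes. Fewer calls under stricter limits follow from their construction, as do smaller folds of dim genes after the normexp offset, and for the other changes the cause was not tested. Dim signals limit the fold of genes near background.

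For shEZH2.1 and shEZH2.2 against control, their mean, shEZH2.1 against shEZH2.2 and the same way with both, the counts of changed genes were 3514, 5256, 3373, 4830 and 1411. They were 1188, 2843, 1211, 3046 and 361 after normexp correction, 11956, 13992, 13255, 13003 and 5983 by adjusted p alone, and 964, 1780, 846, 1863 and 284 with a 2-fold limit. In the authors' matrix they were 1525, 3297, 1512 and 478, without the comparison of the hairpins, which stayed within 1.5 times. The correlation of fold changes was 0.335 after normexp correction, 0.348 in the authors' matrix and 0.438 without a filter. With each group's arrays averaged, limma called 0 genes in the mean of both hairpins, 0 by adjusted p alone and 923 at an unadjusted p under 0.05.

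Leaving out 1 array at a time, EZH2 ranged from -1.57 to -1.51 with shEZH2.1 and from -1.76 to -1.70 with shEZH2.2. The counts ranged from 2907 to 4301, 4891 to 5355, 2921 to 3933, 4703 to 5261 and 1133 to 1590, the correlation from 0.385 to 0.418 and the lists that shifted in the mean of both from 8 to 11.

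The replicate numbers did not pair the arrays. Deviations from the group means correlated at -0.13 to 0.11 in the 9 same-numbered pairs, with 1 over 0.1, and at -0.27 to 0.21 in other pairs, and 1 array matched its own number best. With the number as a replicate block, the counts were 3403, 5159, 3289, 4802 and 1328, and 9 lists shifted. With the slide as a random block they were 3621, 5285, 3420, 4856 and 1429.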

Other observations

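The interferon tests below were chosen only after the results were seen, while the tests of neighbouring genes and of other splits were planned. Epithelial genes moved both ways, with 3 of 29 higher and 4 lower in the mean of both hairpins (camera adjusted p = 0.286). The epithelial transcription factor ELF3 rose by 1.76 with shEZH2.1 and 2.30 with shEZH2.2 (SE 0.10 for each), while the splicing regulator ESRP2 fell by 0.88 and 0.74 (SE 0.08 for each). Of 34 replication-dependent histone genes 5 rose and 7 fell (median -0.12, mean -0.02, camera upward with adjusted p = 0.884), with H2AC18 at 1.91 (SE 0.07) and H1-1 at -1.83 (SE 0.06). Of 32 genes reported as repressed by EZH2 in cancer cells 5 rose and 3 fell (adjusted p = 0.237), and the growth inhibitor DIRAS3 rose by 1.81 (SE 0.10). The hairpins differed in sign on this list, with a median of 0.14 with shEZH2.1 and -0.13 with shEZH2.2. Over the settings with the same limits and 1 value per gene, 5 to 7 members rose and 0 to 2 fell with shEZH2.1. With shEZH2.2, 7 to 8 rose and 4 to 8 fell. Of 31 invasion and matrix protease genes 4 rose and 1 fell (adjusted p = 0.0504), with the plasminogen activator PLAT at 1.97 (SE 0.08). Over the settings with the same limits and 1 value per gene, 3 to 5 of them rose and 1 to 3 fell. Without shEZH2.1 replicate 3, 4 rose and 3 fell. Of 36 Wnt pathway genes 2 rose and 5 fell (adjusted p = 0.884), with the Wnt inhibitor SFRP1 at -1.32 (SE 0.08).

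In the mean of both hairpins, none of the members of 7 lists passed the limma test at both limits. The members under an unadjusted p of 0.05 were 10 of 18 PRC1 subunits, 17 of 28 HOX genes, 26 of 48 mitosis genes, 9 of 13 CDK inhibitors and G1 cyclins, 5 of 19 antigen presentation genes, 17 of 30 unfolded protein response genes and 12 of 48 ribosomal protein genes. Over all 24624 tested genes, 13255 (53.8%) were under 0.05 by limma adjusted p alone. That limit is stricter, so the share by unadjusted p is at least as high, and these counts do not by themselves mark the lists. The antigen presentation and ribosomal protein lists lay well under that share. Their camera adjusted p values were 0.884 for the PRC1, HOX, CDK and antigen presentation lists, 0.0504 for mitosis, 0.161 for the unfolded protein response and 0.283 for the ribosomal proteins. Over the settings with the same limits and 1 value per gene, 0 to 4 HOX genes rose and 0 to 1 fell in the mean of both hairpins. With shEZH2.2 alone, 3 to 6 HOX genes rose and 1 to 2 fell. Camera gave adjusted p = 0.322 for the 11 PRC2 subunits and for 52 developmental transcription factors, of which 5 rose and 8 fell, with 1 to 5 and 1 to 11 over the settings with the same limits and 1 value per gene. With shEZH2.1 that list had 2 higher and 9 lower members (1 to 4 and 2 to 10 over these settings), or 3 and 9 adjusted over the list alone (adjusted p = 0.0424, and adjusted p = 0.429 with an estimated correlation). Its adjusted p was 0.0573 without control replicate 3 and 0.0528 without shEZH2.1 replicate 2. Of 34 mesenchymal genes 7 rose and 4 fell (median -0.07, mean 0.14, adjusted p = 0.731), of 27 aldehyde dehydrogenase and retinoid genes 7 rose and none fell (adjusted p = 0.0671), of 20 NRF2 target genes 3 rose and none fell (adjusted p = 0.72) and of 21 neuronal genes 3 rose and 4 fell (adjusted p = 0.456). Over the same settings 1 to 4 neuronal genes rose and 2 to 7 fell, with 7 falling when shEZH2.1 replicate 3 was left out. Of 16 angiogenesis genes 3 fell and none rose (median 0.08, mean -0.10, adjusted p = 0.884), and of 15 ovarian stem cell markers 2 rose and 3 fell (median -0.12, mean 0.07, adjusted p = 0.853). Of 15 cancer-testis antigen genes 5 rose (adjusted p = 0.283), of 33 histone methylation and demethylation enzymes 2 fell (adjusted p = 0.237), of 9 fibroblast markers 5 rose and 1 fell (adjusted p = 0.0504) and of 8 endothelial markers 1 rose (adjusted p = 0.884). Of those 9 fibroblast markers 7 are also in another list and 7 were well above background on all control arrays, and for the endothelial markers these numbers were 1 and 7.

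The fall of the interferon-stimulated genes with both hairpins was weighed against technical causes. Scaling was not its whole cause, since the weakest list median over 5 other scalings or sources of values was -1.16. A difference between slides cannot be told apart from the knockdown, since no slide holds controls and a hairpin, and the shEZH2.1 array on slide 3 differed from those on slide 2 by a list median of -0.19. The smaller of the list's median changes was 4.03 times its spread between arrays of a group (0.227), but no group holds cultures known to be separate, so an interferon tone that varies between cultures may remain and cannot be told apart. An effect of EZH2 loss also remains, as untested.

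The same genes deviated together between arrays of a group, at 0.17, 0.09 and -0.27 in the controls. Of 10000 random lists matched on level, 0 had as large a spread of the median within groups (0.227, against 0.037 for the highest random list), which argues against noise shared by any genes of such levels. Passing 0.037 is not particular to these genes. Ribosomal protein genes (0.058, 48 genes) and mitosis genes (0.051, 48 genes) passed it too, while E2F and DNA replication genes (0.029, 50 genes) did not. The interferon list had the largest spread of the 33 lists. Within the controls, which share 1 slide, 0 of 10000 lists did (0.236 against 0.054), which argues against a difference between slides. The series design calls these arrays technical replicates, and whether the arrays of a group share 1 culture was not tested. No biological explanation was tested.

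Of the genes called the same way with both hairpins, those that rose formed 13 pairs of neighbouring tested genes whose symbols do not share their first 3 characters, against a median of 7 in 10000 random draws (permutation test, one-sided p = 0.019, Benjamini-Hochberg adjusted p = 0.038 over both directions). The pairs include TMPRSS3 with RSPH1 and LY96 with GDAP1, where RSPH1 and GDAP1 were chosen after their values were seen. Genes that fell formed 13 such pairs against a median of 14 (permutation test, one-sided p = 0.69, adjusted p = 0.69). These include MX2 with MX1 and CD6 with CD5, related genes with short symbols that this rule did not remove, the latter chosen after their values were seen. With pairs that share 3 characters included, those that fell formed 24 pairs against a median of 15 (permutation test, one-sided p = 0.022, unadjusted) and those that rose 14 against 7 (p = 0.016, permutation test). That neighbouring genes were released together is a hypothesis consistent with the 13 pairs that rose, while for the genes that fell the excess is in pairs that share them.

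Other splits of the arrays were drawn to ask whether chance can be excluded. For a single hairpin against control and for the hairpins against each other, the 6 arrays allow 10 splits, too few for a share under 0.05. In each of the 3 cases 1 split, the real one, gave as many genes (3369, 5350 and 4743, against 0 for the highest other). Of 100 drawn splits of the 9 arrays, the real one included, 3 called as many genes in the mean of both hairpins (real 3373, highest other 4250). For calls the same way with both, 3 splits gave as many (real 1411, highest other 2996). Splits that mix arrays of different groups widen the spread within groups and so call few genes by construction. The small shares therefore do not exclude chance for either count. The series design calls the arrays technical replicates, so chance differences between cultures stay open as well. The highest values came from splits in which all 3 shEZH2.2 arrays formed the reference group. In 1 of these all 3 groups were kept whole, so it is the real grouping with another reference and not a chance split. It gave 4250 genes in the mean of both and 2691 calls the same way. For the lists, 19 of 100 splits gave as many (real 9, the study's own list included, highest other 14), so chance is not excluded.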
